A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

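Halobacterium salinarum NRC-1 is a halophilic archaeon, and per the labels' protocols cultures in mid-log phase were exposed to nickel sulphate for 5 h before total RNA was taken. The series holds 8 two-colour spotted arrays of 4 RNA extracts: a control culture and cultures given 0.5, 0.75 or 1.5 mM nickel. Each extract was hybridised on 2 arrays with the Alexa dyes exchanged between channel 1 and channel 2, against a common control reference RNA. The arrays of 1 extract share their RNA, so they were averaged and counted as 1 replicate. The labels do not say that the extracts came from separate experiments, so p-values measure the spread between these extracts, which may be technical. The nickel extracts differ in dose, so their spread and SD also hold any difference between doses.

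The deposited table, per the file headers, gives 1 log ratio of the 2 dyes for each of 10752 spots on each array; the base of the logarithm, the ratio's formula, the centring and the normalization are not given in the sources used here. Raising 2, e or 10 to the values gave no ratios of whole numbers, so the base stayed open and changes are printed in the table's own log units. No scanner intensities were analysed here, so signal over background is unknown, and the number of arrays limits the precision. The medians of the deposited values over all spots were 0.130, 0.145, 0.145 and 0.188 on the arrays with the culture's own RNA in channel 1, in order of dose from the control culture, and 0.133, 0.200, 0.206 and 0.221 on those with it in channel 2. The arrays were therefore not centred on 0.

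An exact 0 was treated as a failed value. Such values numbered 326, 74, 442 and 1 on the channel 1 arrays and 50, 189, 8 and 0 on the channel 2 arrays, in the same order. Both arrays of the control culture also had 884 spots without a value. The table repeats in a pattern of 4 spots per feature, made of a pair of adjacent spots printed in each of 2 copies, and the mean over the spots was used for each of 2688 features. A further choice, made after the values were seen, left out 286 features that lacked spots on the control culture's arrays. Another 18 lacked a value on some array. The remaining 2384 features were tested.

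The platform annotation, whose symbols can be old, gives 133 features 1 gene symbol each, and no feature has several. Of these, 132 were tested and gatC was left out. The other features are unnamed here. The gene table at hand is of another strain, 91-R6, and none of its gene numbers matched, so no coordinates are given. In that table panB is also a synonym of a proteasome nucleotidase, so the identity of this symbol is uncertain. Of the genes to be named in any case, zntA, yvgX, sirR, idr1 and idr2 were not analysed here.

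The orientation of the swapped arrays departed from the rule fixed before the data were examined. That rule took swapped arrays as already turned where the arrays of a pair correlated above 0 as deposited, and the r across features was 0.737, 0.748, 0.745 and 0.775 for the 4 pairs. The arrays were nevertheless turned, for reasons seen in the data. The 286 left-out features had medians of 0.695, 0.696 and 0.678 on the nickel arrays of one orientation and 0.821, 0.859 and 0.802 on those of the other, the same sign in both. Features with a failed spot had a median pair mean of 0.481, against 0.0993 for the others, so the pair mean as deposited followed spot quality. These values point to a fixed dye direction in the table, but no source states it. With the arrays turned, the nickel minus control differences correlated at -0.334, -0.310 and -0.106 between the 2 orientations at 0.5, 0.75 and 1.5 mM, and the consensus correlation between the arrays of an extract was -0.360. Unturned, the nickel minus control differences correlate with the opposite sign, so these values count against the turning, and the orientation stays unsettled. The reading that was fixed first is given as an alternative. The order of names in the array descriptions, first over second, gave the likely direction of each ratio.

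For each extract the oriented log ratio was the mean of its 2 arrays after the sign of the swapped one was turned. Nickel was compared with the control culture by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment at 0.05) over 3 nickel extracts and 1 control culture, which was assumed to vary like the nickel extracts. The arrays may go against this: r between printed copies was 0.616 and 0.769 on the control arrays and 0.886 to 0.938 on the nickel arrays. That r covers more left-out features on the nickel arrays, so the sides are not compared like with like. The SD between adjacent spots was 0.0372 and 0.0381 on the control arrays and 0.0373 to 0.0411 on the nickel arrays. The trend was the slope on dose in mM over the 4 extracts in the same tool. Each dose has 1 extract, so it has no test and is described by its size on both arrays. Size thresholds depend on the base: 2-fold is 0.301 log units if the base is 10, and 1 if it is 2.

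Of 22 gene lists fixed before the data were examined, 13 had a named member tested and 9 had none: metal efflux, metal-dependent regulators, siderophore synthesis, RNA polymerase, general transcription factors, gas vesicles, ATP synthase, transposases and iron-sulphur cluster assembly. The 7 lists with at least 3 members were tested with limma's camera (preset correlation 0.01) against the 132 named genes. This background, the minimum of 3 and the match of tRNA ligases by symbol were chosen once the table had been seen. The rule for named genes took up to 12 in each direction with the same direction on all 6 nickel arrays, called ones first, and the 3 members of each list with the largest changes. It was applied to features with a symbol, with at most 2 unnamed features each way.

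The fit was tested on simulated data over 2384 features. For nickel against control culture it recovered 23.9% of changes of 0.1 log units, 91.0% of 0.2 and 98.5% of 0.3, with 11 false among 153 calls. For the dose trend it recovered 46.3% at 0.1 log units per mM, 95.5% at 0.2 and 100% at 0.3, with 7 false among 168 calls. In both simulations the control extract had the same spread as the nickel extracts, and noise that differs between dye orientations was left out. The real arrays of an extract had a consensus correlation of -0.360, so these rates hold only under the simulation's own assumptions. Alternatives covered the control used, centring, scaling, each dye orientation alone, the extract as a random block, the summary over spots, robust eBayes, each nickel extract left out, the sign and the size threshold. Alternatives added after the data were seen covered unturned arrays, a loess of the oriented ratio on the pair mean (span 0.3), a running median along print order (101, 51 or 201 features wide), the features left out, all 4 spots present and each printed copy alone. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.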

Results

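The measurements were log ratios of RNA from Halobacterium salinarum NRC-1 cultures to a common control reference, on 8 arrays of 4 extracts. There was 1 extract of an untreated control culture and 1 each of cultures given 0.5, 0.75 or 1.5 mM nickel sulphate for 5 h. The question the design poses is which transcripts differ under nickel, and whether they follow the dose. Signs below take the first-named RNA of each array description as the numerator, which is likely but not stated. If the ratio runs the other way, every sign turns and the calls become 16 higher and 20 lower.

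The 3 nickel extracts differed from the 1 control extract in 3 named genes; the control has no spread of its own, so the test cannot separate nickel from a peculiarity of that extract. Transcripts of pyrF, orotidine phosphate decarboxylase of pyrimidine synthesis, rose by 0.24 log units (SE 0.0417, limma adjusted p = 0.0289), and those of mutL, a mismatch repair protein, rose by 0.21 (SE 0.0368, limma adjusted p = 0.0289). Transcripts of dpsA, a ferritin-like DNA-binding protein, fell by 0.20 (SE 0.0422, limma adjusted p = 0.0458). Each kept its direction on all 6 nickel arrays, but all 6 were compared with the same control extract, so these directions are not independent. By their titles these 6 arrays are numbered in 1 run, and the control arrays lie outside it. The 884 spots without a value occur on both control arrays and on no nickel array. Nickel therefore cannot be separated from this difference between array groups either. The oriented log ratio of pyrF was -0.33 in the control culture and -0.0891 ± 0.0505 (SD, n = 3) under nickel. That of mutL was -0.22 and -0.0162 ± 0.0308 (SD, n = 3), and that of dpsA was 0.28 and 0.0746 ± 0.0525 (SD, n = 3). If the log base is 10, these changes are 1.74-fold for pyrF, 1.61-fold for mutL and 1.60-fold for dpsA; if it is 2, they are 1.18-, 1.15- and 1.15-fold. The mean of the pairs as deposited was 0.361 for pyrF and 0.445 for mutL, nearer to the median of features with a failed spot (0.481) than to that of the others (0.0993), and -0.16 for dpsA. On the channel 1 control array the second printed copy of pyrF and mutL held exact 0 values, which were treated as failed. No alternative kept these values. At the first copy alone pyrF stood at 0.175, mutL at 0.187 and dpsA at -0.15, none past the test; dpsA passed at the second copy alone (-0.25, limma adjusted p = 0.00105). None of the 3 passed with channel 1 arrays alone, nor did pyrF with channel 2 arrays alone (0.14, limma adjusted p = 0.0648). Tested against the reference in place of the control culture, all 3 took the other sign. There pyrF and dpsA passed the test in that opposite direction (limma adjusted p = 0.00523 and 0.0138), while mutL did not. A running median along print order brought pyrF to between 0.143 and 0.150, no longer past the test. The call of dpsA ended with a change of -0.19 after a running median of 101 features (limma adjusted p = 0.0570) but held at widths of 51 and 201 (limma adjusted p = 0.0369 and 0.0345). It also ended at -0.16 after a loess on the pair mean and at -0.17 with centring and scaling (limma adjusted p = 0.104 and 0.0905).

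The same direction on all 6 nickel arrays was seen for 28 named genes, 7 higher and 21 lower, most of which did not pass the test. The arrays were not centred, and the median change over all features was -0.0259. With arrays centred, 15 named genes lay higher and 10 lower on all 6 arrays. Above the control culture lay panB at 0.17 (limma adjusted p = 0.0554), cobN, a cobaltochelatase subunit, at 0.0754, the transducers htr1 at 0.0588 and htr8 at 0.0540, and the proteasome subunit gene psmB. Below it lay rpl12p, of the ribosomal stalk, at -0.19 (limma adjusted p = 0.0641) and sucC, a succinyl-CoA synthetase subunit, at -0.17 (limma adjusted p = 0.0525). Smaller differences, none past the test, were those of guaB, for IMP dehydrogenase, at -0.12, ndk, for nucleoside diphosphate kinase, at -0.11, carB, for a carbamoyl phosphate synthase subunit, at -0.11, pyrB at -0.10 and pyrI at -0.0852. The ferredoxin gene fer2 lay at -0.10, arcA, for arginine deiminase, at -0.0993, and gyrA and lysS, for DNA gyrase and a tRNA ligase, were also lower. With dpsA, these make up the 12 lower genes with the largest differences. Among the 132 named genes, 42 estimates were above the control culture and 90 below with arrays turned but not centred. The counts were 62 above and 70 below with arrays centred, and 69 above and 63 below centred and scaled. Adjusted over the named genes alone, 6 passed: pyrF, mutL, dpsA, sucC, panB and rpl12p.

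**Figure D1:**
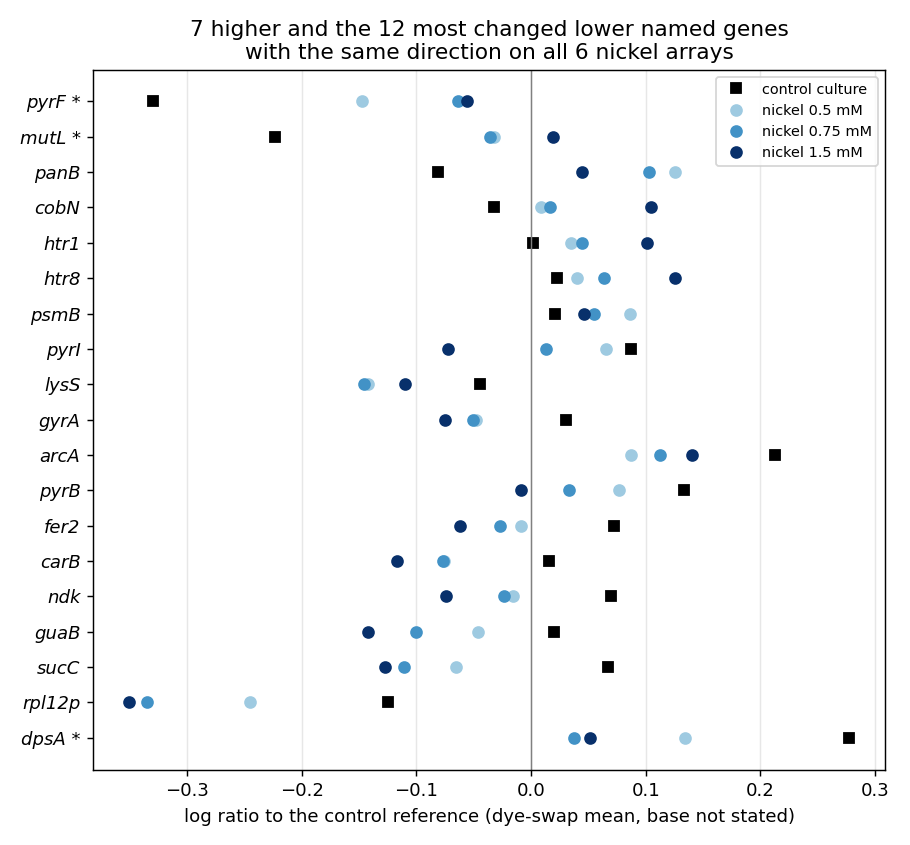
Oriented log ratio to the control reference (horizontal axis, log units of unstated base) for 19 of the 28 named genes with the same direction on all 6 nickel arrays, the 7 higher and the 12 lower with the largest differences; each point is 1 extract as the mean of its 2 arrays, the square is the control culture, and stars mark limma adjusted p under 0.05. The control culture lies at -0.33 for pyrF and 0.28 for dpsA. Its place outside the nickel extracts of each gene follows from how the genes were chosen.

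Over all 2384 features, limma called 36, of which 20 were higher and 16 lower, and 34 of the 36 had the same direction on all 6 nickel arrays. Of these calls, 11 lack a printed copy on some array, control or nickel. Every difference is taken from the control culture, whose arrays had the lower r between printed copies. It was 0.616 and 0.769 there, against 0.886 to 0.938 on the nickel arrays. That r covers more left-out features on the nickel arrays, where their medians were 0.678 to 0.859, against 0.112 to 0.172 for tested features. The SD between adjacent spots was similar, 0.0372 and 0.0381 on the control arrays and 0.0373 to 0.0411 on the nickel arrays. The unnamed feature at spot 4095 rose by 0.30 (limma adjusted p = 0.0308) and that at spot 761 by 0.29 (limma adjusted p = 0.0106), while those at spots 1605 and 3363 fell by 0.24 each (limma adjusted p = 0.0289 for both). With arrays centred on their medians the calls were 100, 79 higher and 21 lower; centred and scaled, 36, 34 higher and 2 lower. The calls became 0 with channel 1 arrays alone (379 at an unadjusted p under 0.05), 504 with channel 2 arrays alone, 201 without the 1.5 mM extract, and 1162 against the reference. They became 12 after a loess on the pair mean, all higher, and 25, 40 and 40 after running medians of 101, 51 and 201 features, with 4, 8 and 7 of them lower. They became 65 with the features left out, and 8 or 55 from the first or second printed copy. With swapped arrays left unturned, as the rule fixed first would have it, the calls were 394, sharing 6 with the 36. There dpsA lay at 0.0709 in place of -0.20, with pyrF at 0.10 and mutL at 0.0153, none of them past the test. In contrast sucC, not past the test with arrays turned, lay at -0.12 with arrays unturned, in the same direction and past the test.

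The gene lists gave no call. Of the 7 lists tested by camera in limma, 0 passed after adjustment and 2 had an unadjusted p under 0.05, of which 0 did so with an estimated correlation. In DNA repair, 3 of 4 members lay higher, or 4 of 4 with arrays centred: mutL rose, uvrA stood at 0.0345 and radB at -0.00260 (limma camera adjusted p = 0.103, and adjusted p = 0.631 with an estimated correlation). In chaperones and proteolysis, 4 of 6 members lay higher, led by panB at 0.17 and pan1, a proteasome-activating nucleotidase, at 0.0842, though pan1 stood at 0.0219 at the copy measured on all arrays, while the chaperone gene dnaK stood at -0.0827 (limma camera adjusted p = 0.128, and adjusted p = 0.861 with an estimated correlation). In flagella and chemotaxis, 7 of 11 members lay higher, or 10 of 11 with arrays centred, htr1 at 0.0588, htr8 at 0.0540 and cheR, a methyltransferase of chemotaxis, at -0.0407 (limma camera adjusted p = 0.128).

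Purine and pyrimidine synthesis went both ways: pyrF rose, while 8 of the 10 members lay lower, or 6 with arrays centred, among them guaB at -0.12 and purM at -0.10 (limma camera adjusted p = 0.787). Of the tRNA ligases, 9 of 12 lay lower, or 7 with arrays centred and 6 centred and scaled, with lysS at -0.0879, aspS at -0.0844 and cysS at -0.0633 (limma camera adjusted p = 0.787). In cobalamin synthesis cobN stood at 0.0754, cbiT at 0.0189 and cbiG at -0.0849 (limma camera adjusted p = 0.718). The 4 genes of the bacteriorhodopsin and carotenoid list, with bat at -0.0279, hop at -0.0246 and sop1 at -0.00613, had a median of -0.0154, which camera places above the other named genes although it is below 0 (limma camera adjusted p = 0.927). That median was 0.00835 with arrays centred, and all 4 genes lay higher with arrays centred and scaled. The genes bat, hop, sop1, purM, cysS and cbiG, and uvrA and radB of the DNA repair list, had opposite signs in the 2 dye orientations. Adjusted over the list alone, mutL, panB and pyrF passed in their lists and no member passed in the other 4.

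Lists with fewer members were described by member. Both ribosomal protein genes lay lower, rpl12p at -0.19 and rpmC at -0.11, and both passed adjusted over the list alone, though neither over all features. The change of rpmC stood at -0.00392 at the first printed copy and -0.22 at the second. Of the oxidative stress list, dpsA fell and msrA, a methionine sulphoxide reductase, stood at -0.0349; adjusted over the list alone, 1 passed. In arginine fermentation, arcC, for carbamate kinase, stood at 0.11 and arcA at -0.0993, and both passed adjusted over the list alone. The gene arcC had opposite signs in the dye orientations, -0.0565 with channel 1 arrays and 0.28 with channel 2 arrays. The genes msrA above and phoU below also had opposite signs in the dye orientations. The respiratory genes sdhC and nuoL stood at -0.0531 and -0.0494, the phosphate transport genes phnE and phoU at -0.0593 and -0.00775, and cbiQ, the only metal uptake gene with a name, at -0.0500. None of these 5 genes passed over its list alone, and phoU took the other sign with arrays centred.

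No named gene passed the test for a dose trend with the turned values before any running median. After a running median of 101 features along print order 4 did: glmS at 0.13 and cobN at 0.11 log units per mM, and pyrB at -0.10 and rpl12p at -0.14 (limma adjusted p = 0.0347, 0.0389, 0.0449 and 0.0262). Without the running median, the rising slope nearest to passing was that of glmS, for glucosamine phosphate synthesis. It was 0.12 log units per mM (SE 0.0262, limma adjusted p = 0.0525). Next among rising slopes was pyrF at 0.17 per mM (limma adjusted p = 0.0674). On the falling side rpl12p stood at -0.15 per mM (limma adjusted p = 0.0625) and pyrI at -0.11 per mM (limma adjusted p = 0.0683). The 7 features that passed were all unnamed and all had positive slopes, and their median pair mean was 0.467, against 0.135 over all tested features. They were led by that at spot 4095 at 0.24 per mM (SE 0.0395, limma adjusted p = 0.0460) and that at spot 191 at 0.23 per mM (SE 0.0277, limma adjusted p = 0.0257). These calls rested on single extracts and settings: they became 0 without the 0.75 mM extract (288 at an unadjusted p under 0.05), 141 without 0.5 mM, 256 without 1.5 mM, and 0 in limma with centred arrays (447 at an unadjusted p under 0.05). After a loess on the pair mean limma gave 0 as well (418 at an unadjusted p under 0.05), with the rank of the dose 97, among the nickel extracts alone 147, and between 89 and 128 after a running median along print order.

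Each dose had 1 extract, so the differences at single doses have no test. The difference of panB from the control culture was 0.21, 0.18 and 0.13 at 0.5, 0.75 and 1.5 mM, and that of pyrF was 0.18, 0.27 and 0.27 at 0.5, 0.75 and 1.5 mM. Differences of mutL were 0.19, 0.19 and 0.24, of dpsA -0.14, -0.24 and -0.23, and of rpl12p -0.12, -0.21 and -0.23 in the same order. At 1.5 mM glmS stood at 0.18 and cobN at 0.14, and guaB at -0.16. No feature at 0.5 mM, 1 at 0.75 mM and 5 at 1.5 mM reached 2-fold with the same sign on both arrays if the base is 10, all of them higher, and 0 at any dose if it is 2. The sign was the same on both arrays for 38.1%, 39.9% and 43.0% of features, below the share that independent arrays would give.

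With the arrays turned, the control culture itself departed from the reference as far as the nickel cultures did. The SD of its oriented log ratios was 0.0861, against 0.0802, 0.0846 and 0.0834 at 0.5, 0.75 and 1.5 mM, and it correlated with them across features at 0.739, 0.714 and 0.554; features are not independent replicates. All 11 flagella and chemotaxis genes lay above the reference in the control culture and at 1.5 mM, and 9 of 11 at each of the other doses. Both ribosomal protein genes lay below it in all 4 extracts, with medians of -0.15 in the control culture and -0.26, -0.32 and -0.33 under nickel.

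**Figure D2:**
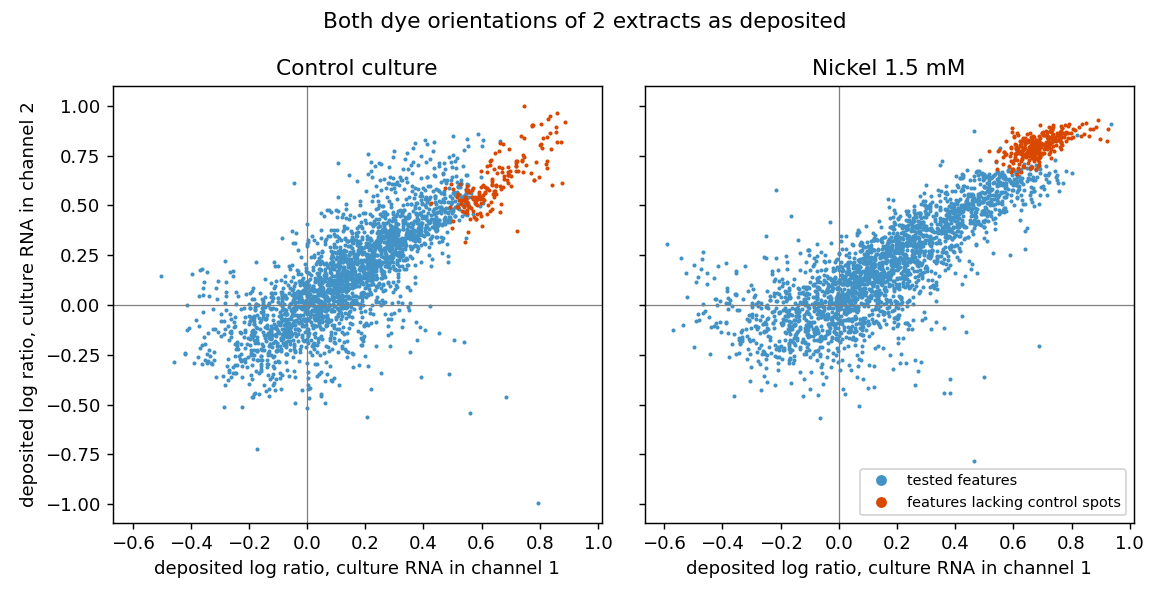
Deposited log ratios of each feature with the culture's RNA in channel 1 (horizontal) against channel 2 (vertical), in log units of unstated base, for the control culture and the 1.5 mM extract; blue points are tested features and orange ones the features lacking control spots. Points run along the rising diagonal in both panels, with r of 0.737 and 0.775 across features.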

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

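All tests of explanations in this part were chosen after the result was seen. Among 175 features that lack spots on the control culture's arrays but have a value on each array, 9 were called, all lower, with a median change of -0.0856 over the 175. These lie outside the comparison, since none has all its spots on the control arrays.

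Some named genes stood above the control culture on both arrays of one dose and below it on both arrays of another; the difference was not tested. The gene serS stood at 0.0391 at 1.5 mM and -0.0468 at 0.5 mM, gdhA1 at 0.0362 at 0.5 mM and -0.0552 at 0.75 mM, and purF at 0.0461 at 0.5 mM and -0.0741 at 1.5 mM. The gene sop2 stood at 0.0169 at 0.75 mM and -0.0250 at 0.5 mM, radB at 0.0583 at 1.5 mM and -0.0363 at 0.5 mM, and cheA at 0.0276 at 0.5 mM and -0.0185 at 1.5 mM.

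The control culture departed from the reference in much the same features as the nickel cultures, with r of 0.714 to their mean. A position effect is argued against by an r of 0.706 between one printed copy of the control culture and the other copy of the nickel mean. A smooth trend on the pair mean is argued against by an r of 0.730 after it was taken off. The pair mean is not an intensity, so an intensity-dependent dye effect was not tested. A reference RNA that differs from every culture may account for the shared departure, with r of 0.719 across copies after the trend on the pair mean was taken off. If the turning is right, an equal dye effect cancels in each pair. Dye effects of single features that differ between orientations do not cancel and cannot be told apart from a differing reference RNA. The left-out features had medians of 0.678 to 0.696 in one orientation of the nickel arrays and 0.802 to 0.859 in the other. If the swapped arrays were already turned in the table, the oriented mean holds the equal dye effect of each feature. That could recur in every extract, so this explanation stays open too.

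The calls of pyrF and mutL rest on a control array where a printed copy held exact 0 values, treated as failed. Of the 36 calls, 11 lack a printed copy on some array, control or nickel. At the copy measured on all arrays the change of pyrF was 0.175, more than 1 SE below its 0.24, so the missing copy may have enlarged it. For mutL that change was 0.187, within 1 SE of its 0.21, which argues against it. A nickel effect on either gene remains open.

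All 7 features called for dose had positive slopes, with a median of 0.195 and a median SE of 0.0278; their median pair mean of 0.467 was close to that of features with a failed spot, 0.481. The median was 0.175 after the trend on the pair mean was taken off and 0.199 after a running median along print order, so neither trend is the whole cause. The loess still ended all 7 calls: the median SE was then 0.0257 and the lowest limma adjusted p = 0.0864, with the median unadjusted p going from 0.000115 to 0.000289; the cause of this was not tested. A response to dose may remain as a hypothesis, with 1 extract per dose.

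For the 36 calls, setting each of the 4 extracts alone against the others gave 36 for the control culture and at most 0 for another, so 1 of 4 splits reached the count. That is too few splits for a share under 0.05.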

How the results depend on the processing

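The turning of the swapped arrays in the reported values was itself chosen after the data were seen; leaving them unturned is the reading fixed before, kept as an alternative added later. The tests with the loess, the running medians, the features left out, all 4 spots present and each printed copy were chosen after the result was seen; the others were fixed before the data were examined. Over 40 named genes and 20 alternatives, 794 changes were recomputed: 706 kept their direction and 88 reversed; of the former 15 lost and 53 gained a call, and of the latter 2 lost and 7 gained one; where no reason follows, the cause was not tested. A further 2 of the reversed changes were called in both directions, those of pyrF and dpsA against the reference. Leaving swapped arrays unturned reversed 27 of the 40, so the directions rest on the orientation. Signal over background is unknown. No paired analysis was possible because the arrays of an extract are dye swaps, replicate numbers were given in accession order and each dose has 1 extract. The alternative with genes on all 8 arrays equals the reported fit, and admitting features measured on a lone array of an extract was not run, since their values would mix lone orientations with pairs.

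The 36 calls for nickel became 1162 against the reference (327 higher, 835 lower), 100 with arrays centred (79 higher, 21 lower), 0 with channel 1 arrays alone (379 unadjusted, limma), 504 with channel 2 arrays alone (126 higher, 378 lower), and 30 to 201 with a nickel extract left out, the highest without 1.5 mM. They became 394 with swapped arrays not turned (275 higher, 119 lower), 12 after the loess (12 higher, 0 lower), 65 with the features left out, and 8 and 55 from the first and second printed copy. By size, 0 reached 2-fold if the base is 10 and 0 if it is 2. Similar counts need not mean the same features. The centred and scaled, running median and all 4 spots settings shared only part of their calls with the reported fit. Within 1.5 times of 36 were 54 with the extract as a random block, 32 with the median over spots, 36 with robust eBayes, 36 centred and scaled (34 higher, 2 lower), 25, 40 and 40 after running medians (21, 32 and 33 higher) and 31 with all 4 spots.

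The 7 calls for dose became 97 with the dose rank, 147 among nickel extracts alone, 0 to 256 with a nickel extract left out, 0 with arrays centred, 0 after the loess, 89, 95 and 128 after running medians of 101, 51 and 201 features, 1 with the features left out, 4 with all 4 spots, and 42 and 64 from the first and second printed copy. Features past 2-fold if the base is 10, 0, 1 and 5 in order of dose, became 8, 22 and 20 against the reference, 1, 2 and 11 with arrays centred, 4, 6 and 27 with channel 1 arrays, and 34, 61 and 49 with channel 2 arrays. At 1.5-fold they were 30, 41 and 101. Among the gene lists, 1 passed against the reference, flagella and chemotaxis (limma camera adjusted p = 6.5e-07, against 0.128 to 0.335 over the other settings run on this contrast with the preset correlation), and 0 under the others.

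The change of each gene that reversed follows. Against the reference it was pyrF -0.0891, mutL -0.0162, dpsA 0.0746, pyrB 0.0338, arcA 0.113, pyrI 0.00209, hop 0.0714, sop1 0.0338, pan1 -0.0550. It was also cbiT -0.0895, cheR 0.0649, msrA 0.0249. With swapped arrays not turned it was cobN -0.0154, dpsA 0.0709, rpl12p 0.0754, guaB 0.0843, carB 0.0476, fer2 0.0240, pyrB 0.0565, arcA 0.0330, gyrA 0.0261. It was also lysS 0.0229, sdhC 0.0254, nuoL 0.0488, arcC -0.17, bat 0.11, hop 0.0978, dnaK 0.0806, cbiG 0.101, uvrA -0.17. It was also radB 0.00701, cheR 0.0289, cbiQ 0.0284, msrA 0.0737, phnE 0.0300, phoU 0.0932, purM 0.102, aspS 0.0436, cysS 0.0696. With channel 1 arrays alone it was arcC -0.0565, bat 0.0833, hop 0.0732, cbiG 0.0163, uvrA -0.139, radB 0.00441, msrA 0.0388, phoU 0.0854, purM 0.000166. It was also cysS 0.00629. With channel 2 arrays alone it was sop1 0.0315. With arrays centred it was sop1 0.0176, radB 0.0211, phoU 0.016. With arrays centred and scaled it was bat 0.00165, hop 0.00721, sop1 0.0154, radB 0.0158, phoU 0.0369. After the loess it was bat 0.000532, hop 0.00872, sop1 0.0152, radB 0.014, phoU 0.0137. After a running median of 101 features it was bat 0.01003, sop1 0.0123, radB 0.000235, cheR 0.00346, phoU 0.032. With 51 features it was sdhC 0.00368, hop 0.0134, sop1 0.00378, radB 0.011, phoU 0.0361. With 201 features it was bat 0.000475, hop 0.000949, sop1 0.00751, radB 0.0115, phoU 0.0251. From the first printed copy it was bat 0.00337, hop 0.00654, cbiT -0.0246, radB 0.0144, phnE 0.0132, aspS 0.000778. From the second printed copy it was sop1 0.0112, phoU 0.0181. Without a nickel extract radB lay between -0.0330 and 0.0143.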

Other observations

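The tests of lists in this part were chosen after the values were seen. All 6 named genes of the citric acid cycle lay lower under nickel, with sucC at -0.17, icd at -0.10 and citZ at -0.0761. In limma's camera their unadjusted p was 0.0204 and the adjusted p = 0.102, or adjusted p = 0.655 with an estimated correlation. All 6 lay below the reference at each nickel dose, while 4 of 6 lay above it in the control culture. With arrays centred all 6 still lay lower than in the control culture, and 5 of 6 centred and scaled. The change of sucC rested mostly on 1 dye orientation, at -0.29 with channel 1 arrays alone and -0.0466 with channel 2 arrays alone. Of 6 histidine synthesis genes, 5 lay higher, with hisI at 0.0631 and hisG at 0.0571 but hisF at -0.0671 (limma camera adjusted p = 0.133).

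In histidine degradation, hutU stood at 0.0601 and hutI at -0.0263, with a list median of -0.0106, or 0.0131 with arrays centred (limma camera adjusted p = 0.498). Of 4 glutamate and glutamine genes, 2 lay higher, gdhB at 0.0434 and glnA at 0.0222, and 2 lower, gdhA1 at -0.0268 and gdhA2 at -0.0126, or 3 higher with arrays centred and 4 centred and scaled (limma camera adjusted p = 0.482). In thiamine synthesis, thiL stood at -0.12 and thiD at 0.0553, with a list median of -0.0207, or 0.00296 with arrays centred (limma camera adjusted p = 0.966), and thiL passed adjusted over that list alone.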
